A study of Mus musculus with 15 samples.

How the data were processed

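Chromatin accessibility was measured by ATAC-seq in CD4+ T cells of IRF5+/+ and IRF5-/- mice, untreated (0 h) and 72 h after activation. Peak lists were used for 15 libraries: 4 wild type and 3 knockout at 0 h, and 4 of each genotype at 72 h. The knockout libraries at 0 h carry the replicate numbers 1, 3 and 4. The 23 files are 15 lists for single libraries, 4 lists for merged replicates and 4 final lists per condition, and every file and column was assigned to a group. Per the file headers, wild-type library 4 was made at both times from an alignment numbered 5.

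According to the submitters' processing notes, reads were trimmed with Trim Galore 0.5.0 and aligned to mm10 with Bowtie2 2.2.9, peaks were called with MACS2 2.1.1.20160309, and HOMER 4.10.4 was used downstream. Per the file headers, MACS2 ran on read pairs without a control, kept 1 fragment per position and reported peaks at a q value cutoff of 0.05. The deposited pileup height is the MACS2 fragment coverage signal at the summit of a peak. The deposited fold enrichment is the ratio MACS2 computed of that pileup to its local background. The deposited −log10 p and −log10 q values were computed by MACS2 against the same background, per the file headers. These scores are the authors' and were used only within a list, to rank or filter its peaks. How the final lists were chosen from the merged lists is not given in the sources used here. They hold 55.5% to 74.0% of the merged peaks, and at least 99.8% of their peaks overlap peaks in all libraries of the group or all but 1.

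The per-library lists were merged into a union of 111393 regions. A region was called in a library if a peak overlapped it by at least 1 bp. The 83743 regions called in at least 2 libraries were tested, and 27650 seen in 1 library were not. Depth came from the headers: between 20.5 M and 29.0 M fragments per library after duplicate removal, which limits the calling of weak peaks. Presence or absence of a peak is a threshold measure, so a region without a peak is not shown to be closed.

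Activation was tested for each region with genotype as stratum, and genotype with time as stratum, by a two-sided exact conditional (stratified hypergeometric) test on the number of libraries with a peak. Benjamini-Hochberg adjustment was made over all tested regions, and calls were made at an adjusted p under 0.05. The smallest p this test can give is 0.000408. Regions called in every library of a group and in none of the other group were counted as separating. Peaks per library, bases covered, the share of peaks within 1 kb of a gene boundary and the overlap of peak lists (Jaccard index of bases, within minus between groups) were compared by two-sided exact permutation, whose smallest p is 0.0286, with adjustment over the 4 main comparisons. For the Jaccard index, 35 splits of the libraries were counted.

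Genes came from a reference table of GRCm38.p6, the assembly behind mm10, with 21883 protein-coding genes. Each region was assigned to the nearest gene within 100 kb, which covered 93.5% of regions. The table gives gene bounds without strand, exons or transcription start sites, so distance was measured to the nearest gene boundary and the finest class is the gene body. Motif shares were not computed because no genome sequence was used here. A list of genes was compared by its relative occupancy: the share of its regions called in a library over the share of all tested regions called, as log2. Groups were compared by exact permutation over all 2450 arrangements within strata, with adjustment over 18 lists. The lists are T cell identity, naive and quiescence, T cell receptor activation, Th1 and cytotoxic, Th2, Th17, regulatory T cell, follicular helper and inhibitory receptors, interferon-stimulated, IRF family other than Irf5, glutamine and amino acid metabolism, mTORC1, glycolysis, cell cycle, ribosome biogenesis, and markers of B cells, myeloid cells, and CD8 and NK cells.

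The groups, comparisons, lists, rule for naming genes and all alternatives except 1 were set before the data were examined. The rule named the targeted gene and Dock2, up to 10 regions per comparison and direction with the highest −log10 q in the merged list of the group that has them, and up to 4 genes per list and comparison with the most changed regions. The alternatives were a stricter −log10 q of 5, an equal number of peaks per library (the strongest 29994), regions called in at least 1 or 4 libraries, coverage of at least 0.5 of a region or peak, bases in place of peaks, a gene distance of 20 kb or of 1 kb to the boundary, a boundary distance of 5 kb, autosomes only, regions taken from the final lists, an unstratified Fisher's exact test, the replicate number as a block, and leaving out each library. An equal number of peaks without the smallest library (39807 in each of 14) was added after the data were seen.

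The tests were checked on simulated data with 83743 regions. With nothing planted they gave 0 calls, also with a library-wide shift that followed each library's real share of called regions. In that shift every activated library lay above every untreated one, but the genotypes overlapped at each time. With 200 changed regions, called at rates of 0.95 and 0.05, none was recovered. With 2000, 44.5% (activation) and 45.7% (genotype) were recovered, and with 15000, 85.7% and 85.8%. At rates of 0.8 and 0.2 none was recovered at any of these sizes. False calls were at most 2.00% of calls. Of 200 simulated lists with raised presence 99.5% were called, and of 200 unchanged lists 6.5%. These lists were random regions, tested for activation only and without a library-wide shift. The 6.5% is therefore not the false-call rate of the list results below, and the list test of genotype was not simulated. Region tests gave the same p as scipy for 60 regions and as full enumeration for the same 60, and 251229 presences matched bedtools 2.31.1 with 0 differences. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.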

Results

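ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, was used to map accessible chromatin in mouse CD4+ T cells. The cells came from mice with an intact Irf5 gene (IRF5+/+, wild type) or without it (IRF5-/-, knockout). Irf5 encodes an interferon regulatory factor best known as a transcription factor downstream of Toll-like receptors. Cells of each genotype were profiled before treatment (0 h) and after 72 h of activation in culture. The 15 libraries made 4 groups, with 4 wild-type and 3 knockout libraries at 0 h and 4 of each genotype at 72 h. Depth was read from the headers of the peak lists: 20.5 M to 29.0 M fragments per library remained after duplicates were removed. The difference in group means, knockout minus wild type, was −0.349 M at 0 h (exact permutation p = 0.857) and −3.00 M at 72 h (exact permutation p = 0.0571). The labels do not state that the libraries of a group came from separate animals or cultures, so the p-values measure the spread between these libraries, which may be technical. Peak scores are the authors' own and were used only to rank or filter peaks within a list.

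The targeted gene was examined first. Irf5 lies on chromosome 6 from 29526130 to 29541869 (mm10) and had 5 regions with a called peak, 3 of them inside the gene. The region from 29526327 to 29528321, at the gene's boundary, was called in all 15 libraries, including all 7 knockout libraries. The region from 29528398 to 29529417 was called in every library except knockout library 4 at 0 h, and the region from 29517091 to 29517631 in every library except wild-type library 1 at 0 h. The other regions were called in 4 libraries (29524134 to 29524485, 2 of each genotype, all at 0 h) and in 3 libraries (29536744 to 29537059, 2 wild-type and 1 knockout, all at 0 h). No Irf5 region differed by genotype (lowest unadjusted exact p = 0.429). The deleted part of the gene is not given in the sources used here, so accessibility at Irf5 does not check the genotype labels. Dock2 (chromosome 11, 34226815 to 34783905) encodes a guanine nucleotide exchange factor needed for lymphocyte migration, and a Dock2 mutation is known from some Irf5-deficient mouse colonies. Of its 20 regions, 5 were called in all 15 libraries and none differed by genotype (lowest unadjusted exact p = 0.143). Called peaks do not test for that mutation, so these values do not show whether the mice carried it. A single Dock2 region, from 34466375 to 34467528, was gained with activation: it was called in all 8 activated libraries and in 1 of 7 untreated libraries.

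The comparison of 72 h with 0 h asked how activation reshaped accessible chromatin in each genotype. Untreated cells were profiled only at 0 h, so activation could not be told apart from 72 h in culture or from differences in preparation. Changes with activation below mean 72 h against 0 h. Libraries at 72 h also had a lower mean share of duplicate fragments (0.155 against 0.23 in wild type, 0.1525 against 0.223 in knockout). Their median peaks were narrower (454.5 against 576.25 bp, 419.5 against 481.3 bp). Activated cells of both genotypes had more peaks. Wild-type libraries went from 45746 ± 3960 (SD, n = 4) to 66068 ± 4618 peaks (SD, n = 4), a 1.45-fold rise in the geometric mean. Knockout libraries went from 39313 ± 8231 (SD, n = 3) to 59799 ± 2865 (SD, n = 4), a 1.54-fold rise. Each rise had an exact permutation p = 0.0286, the smallest that groups of these sizes allow, and an adjusted exact p = 0.0571 over the 4 comparisons. The bases covered by peaks rose from 30.8 ± 2.83 to 37.0 ± 1.66 Mb in wild type and from 22.6 ± 5.80 to 31.5 ± 2.08 Mb in knockout (exact permutation p = 0.0286 each). The rise in peak number did not differ detectably between the genotypes (difference of log2 changes 0.09, exact permutation p = 0.739).

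**Figure D1:**
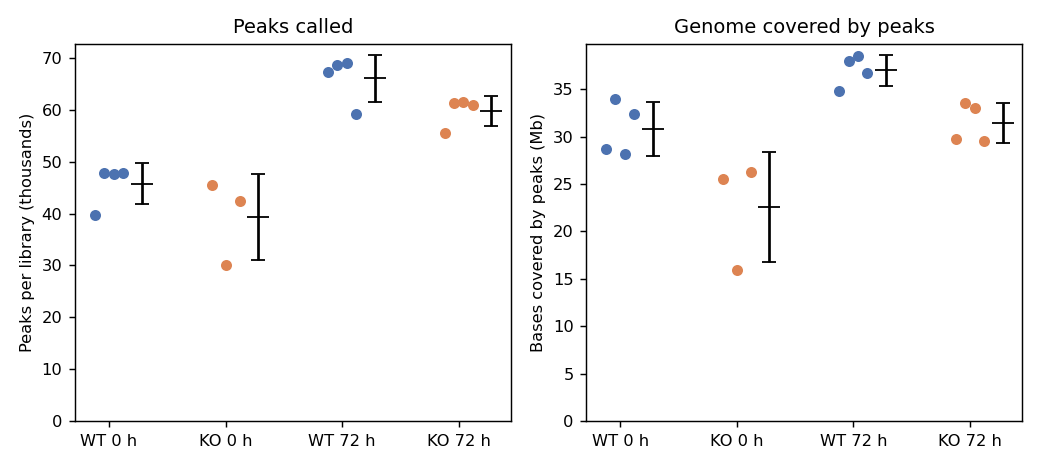
Peaks called (left) and bases covered by peaks (right, Mb) in each library (points; blue, wild type; orange, knockout), with the group mean and SD in black. Activated libraries hold 55519 to 69086 peaks and untreated libraries 29994 to 47790.

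Of 83743 regions called in at least 2 libraries, 21176 (25.3%) had a peak in all 15. With activation, 15380 regions (18.4%) were gained and 3895 (4.65%) were lost in an exact test stratified by genotype, so that 79.8% of the changed regions were gained. When every library was reduced to its 29994 strongest peaks, 6637 regions were gained and 6349 lost, and the gained share was 51.1%. Equal numbers of peaks bring gains and losses near balance by construction, so this value does not show what set the balance with all peaks. Changes in both directions were called either way. Few changed regions lay near a gene's end: 9.73% of gained and 4.83% of lost regions were within 1 kb of a gene boundary. The share was 20.9% of regions that did not change and 45.3% of regions called in all 15 libraries. Regions called in all 15 libraries cannot change and are counted among those that did not, which raises the 20.9%. Changed regions were not compared with the other unchanged regions alone.

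Wild-type and knockout cells mostly changed in the same direction, in tests that shared no library. Of the regions gained completely in wild type, 61.9% were also gained completely in knockout, and of those lost completely 40.8%. In wild type, 11981 regions were called in all activated and no untreated libraries, and in knockout 10791. The lists shared 7420 regions, against 1544 for independent lists. Of the regions lost completely, 2805 in wild type and 1868 in knockout, 1144 were shared, against 62.6 for independent lists. Among the 11981 wild-type gains, 97.6% were called more often after activation in knockout as well, and 24 less often. Among the 2805 wild-type losses, 96.4% were called less often in knockout and 29 more often. Without knockout library 3 at 0 h, which had the fewest peaks, the knockout losses rose from 1868 to 4045.

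The strongest gained regions, ranked by the authors' −log10 q in the merged wild-type list at 72 h, lay mostly outside genes. The first, on chromosome 16 from 87642018 to 87642638 and 46682 bp from Map3k7cl, was called in 8 of 8 activated and 0 of 7 untreated libraries (exact p = 0.000408, adjusted p = 0.00399). The others had as nearest genes Frzb, a secreted Wnt antagonist, Wls, which is needed for Wnt secretion, Tank, an adaptor of NF-κB signalling, Rgs21, Capza1, Tafa2, Pcca, Ypel5 and Rsph14. All 10 were called in all 8 activated libraries and in no knockout library at 0 h. Of wild-type libraries at 0 h, 1 had the regions at Frzb, Wls and Capza1, and 2 had the one inside Pcca (chromosome 14, 122830211 to 122831107). The strongest lost region was on chromosome 13 from 93593323 to 93593965, 22926 bp from Bhmt, and was called in all 7 untreated libraries and no activated library (exact p = 0.000408, adjusted p = 0.00399). Further lost regions lay in the bodies of Eif2a, Gmfb, Trp53inp1, Wwox and Inpp4b, a phosphoinositide phosphatase gene, and nearest to Atp11b, Dnajc5b, Gypc and Tgfbr2, which encodes a receptor for TGF-β. The calls at Gmfb and Tgfbr2 each ended when any of 13 of the 15 libraries was left out, those at Inpp4b and Pcca for 9 and that at Gypc for 2. The nearest gene can be distant, as for the region 397077 bp from Tafa2, and no expression was measured.

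Regions were assigned to 18 lists of genes fixed before the data were examined, holding 305 genes, of which 295 had a region within 100 kb. Of these, 83 had only gained regions, 27 only lost regions, 63 both and 122 neither, with 333 regions gained and 210 lost. For each list, occupancy was the share of its regions with a peak in a library, divided by the same share of all tested regions and given as log2. Between 0 h and 72 h the share of all regions rose from 51.8% to 71.9% in wild type and from 43.8% to 64.8% in knockout. A list can therefore gain more regions than it loses and still fall relative to all regions, as most lists did. Relative occupancy also has an upper limit, reached when all regions of a list are called, which drops as the share of all regions rises. Lists with high occupancy at 0 h are thereby pushed down at 72 h. In wild type the mean share called fell for the naive (72.2% to 64.5%), T cell identity (66.1% to 65.5%) and myeloid (61.5% to 59.8%) lists. It rose for every other list, for example from 65.0% to 82.0% for ribosome biogenesis. By exact permutation stratified by genotype, with Benjamini-Hochberg adjustment over the 18 lists, 16 lists differed: 2 rose and 14 fell. With an equal number of peaks per library, 12 did, 3 higher and 9 lower. Counts of changed regions adjusted over the list alone were the same as those over all regions for 11 lists and are given below for the other 7.

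Genes of the naive and quiescent state showed the most losses. Of the 20 genes in this list, 11 had both gained and lost regions, 5 only lost and 2 only gained ones, and 2 had neither, with 45 regions gained and 65 lost among 503. Foxp1, a transcription factor that keeps T cells quiescent, gained 9 and lost 12 of 95 regions. Bach2, which restrains effector differentiation, gained 7 and lost 8 of 73, and Lef1, a T cell transcription factor of the Wnt pathway, gained 5 and lost 8 of 43. S1pr1, the receptor for exit from lymph nodes, gained 7 and lost 3 of 30. The list's relative occupancy fell by 0.65 on the log2 scale (0.636-fold), with 8 of 8 activated libraries below every untreated library of their genotype (stratified exact permutation adjusted p = 0.000668), and was lower by a similar amount with equal peaks (−0.69, exact adjusted p = 0.00105). T cell identity genes followed: of 20 genes, 11 had changes in both directions, 3 only gains, 1 only losses and 5 neither, with 29 regions gained and 29 lost. Cd28, the costimulatory receptor, gained 4 and lost 5 of 26 regions, Bcl11b, a factor of T lineage commitment, gained 1 and lost 6 of 36, Cd2 gained 5 and lost 1 of 20, and Txk gained 5 and lost 1 of 13. This list fell by 0.53 (0.693-fold, 8 of 8 libraries, exact permutation adjusted p = 0.000668) and stood at −0.81 with equal peaks.

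Genes induced through the T cell receptor had 26 gained and 13 lost regions among 209 (22 and 10 adjusted over the list alone). Of 20 genes, 5 had only gains, 1 only losses, 7 both and 7 neither. Icos gained 4 and lost 4 of 31 regions, Cd44 gained 5 and lost 2 of 21, Il2ra, the high-affinity interleukin-2 receptor chain, gained 3 and lost 2 of 18, and Egr2 gained 4 and lost 1 of 14. Relative occupancy fell by 0.31 (0.805-fold, 8 of 8 libraries, exact permutation adjusted p = 0.000668) and was −0.21 with equal peaks.

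Among the effector programmes, Th2 genes gained 21 and lost 2 of 98 regions, near the 18.4% gained over all tested regions. Of 15 genes, 10 had only gained regions, 1 only lost, 1 both and 3 neither. Il4ra, the interleukin-4 receptor chain, gained 4 of 14 regions, Gata3, the Th2 master regulator, 3 of 16, Maf 3 of 11 and Il24 2 of 2, with none lost. Relative occupancy rose by 0.14 (1.11-fold, 7 of 8 libraries above every untreated library of their genotype, exact permutation adjusted p = 0.00315), and by 0.42 with equal peaks (exact adjusted p = 0.00163), but it was lower among regions within 1 kb of a gene boundary (−0.26, exact adjusted p = 0.000525). Within 20 kb the rise was 0.02 (exact adjusted p = 0.565). Th17 genes gained 26 and lost 10 of 124 regions (27 and 11 adjusted over the list alone). Of 13 genes, 7 had only gains, 4 both and 2 neither. Rora gained 5 and lost 5 of 37 regions, Il21 gained 4 and lost 2 of 19, Ahr gained 3 and lost 2 of 9, and Ccr6 gained 3 and lost 1 of 8. The Th17 list did not differ with all peaks (−0.07, exact permutation adjusted p = 0.438), was higher with equal peaks (+0.25, exact adjusted p = 0.0022) and lower without knockout library 3 at 0 h (−0.16, exact adjusted p = 0.0494).

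Th1 and cytotoxic genes gained 31 and lost 14 of 193 regions. Of 20 genes, 8 had only gains, 3 only losses, 5 both and 4 neither. Il12rb2, the inducible interleukin-12 receptor chain, gained 6 and lost 1 of 17 regions, Stat4 gained 4 and lost 2 of 19, Ifng, which encodes interferon-γ, gained 5 of 26 with none lost, and Fasl gained 1 and lost 3 of 20. The list fell by 0.25 relative to all regions (0.842-fold, 8 of 8 libraries, exact permutation adjusted p = 0.000668), and stood at −0.25 with equal peaks. Regulatory T cell genes gained 24 and lost 17 of 153 regions (26 and 20 adjusted over the list alone). Of 13 genes, 3 had only gains, 1 only losses, 3 both and 6 neither. Nrp1 gained 11 and lost 5 of 38 regions, Ikzf2, which encodes Helios, gained 3 and lost 6 of 30, Ctla4 gained 3 and lost 4 of 19, and Nt5e gained 4 of 14. Follicular helper and inhibitory receptor genes gained 21 and lost 15 of 143. Of these 13 genes, 4 had only gains, 1 only losses, 6 both and 2 neither. Tox gained 4 and lost 9 of 42 regions, Btla gained 4 and lost 1 of 10, Cd200 gained 2 and lost 1 of 11, and Pdcd1, which encodes PD-1, gained 2 and lost 1 of 10. The regulatory list fell by 0.36 and the follicular list by 0.33 (8 of 8 libraries and exact permutation adjusted p = 0.000668 for each). Neither fall passed with equal peaks (−0.03, exact adjusted p = 0.593, and −0.09, exact adjusted p = 0.109).

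Interferon-stimulated genes, a class of targets of the interferon regulatory factors, gained 10 and lost 2 of 63 regions. Of 22 genes, 7 had only gains, 1 only losses, 1 both and 9 neither, and 4 had no region. Ifih1, a sensor of viral RNA, gained 3 of 11 regions, Oas3 gained 1 of 2 and Oasl2 1 of 3. Their relative occupancy did not differ (0.00, exact permutation adjusted p = 0.997). The other interferon regulatory factor genes gained 8 and lost 7 of 67 regions. Of 8 genes, 1 had only gains, 1 only losses, 3 both and 1 neither, and 2 had no region. Irf2 gained 5 and lost 2 of 24 regions, Irf1 gained 1 and lost 3 of 12, and Irf4, a factor induced by T cell receptor signalling, gained 1 and lost 1 of 10. This list fell by 0.28 (0.826-fold, 7 of 8 libraries, exact permutation adjusted p = 0.00113), but with equal peaks it stood at +0.01 (exact adjusted p = 0.938).

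In each list of metabolic and growth genes, more regions were gained than lost with all peaks, while many genes had no changed region. Glutamine and amino acid genes gained 13 and lost 4 of 112 regions (12 and 3 adjusted over the list alone). Of 20 genes, 8 had only gains, 2 only losses, 1 both and 9 neither. Slc7a11, the cystine transporter, gained 4 of 16 regions, Gfpt1 2 of 5 and Phgdh, the first enzyme of serine synthesis, 1 of 4, while Slc38a1 gained 1 and lost 2 of 14. Glycolysis genes gained 16 and lost 5 of 125 (16 and 4 adjusted over the list alone). Of 20 genes, 4 had only gains, 3 only losses, 2 both and 11 neither. Hif1a gained 5 and lost 1 of 20 regions, Pfkp 4 of 14 with none lost, Hk2, a hexokinase gene, 3 of 9, and Pfkfb3 gained 1 and lost 1 of 14. Genes of mTORC1 gained 10 and lost 8 of 83, with 5 of 20 genes showing only gains, 3 only losses and 11 neither, and 1 without a region. All 6 changed regions of Rptor, which encodes raptor, were lost, while Eif4e gained 4 of 11, Rps6 2 of 3 and Deptor 2 of 10. Cell cycle genes gained 16 and lost 8 of 109. Of 22 genes, 4 had only gains, 2 only losses, 3 both and 13 neither. Ccne1 gained 4 and lost 2 of 15 regions, Cdk6 gained 3 and lost 3 of 24, Ccnd2, which encodes cyclin D2, gained 4 of 17 with none lost, and Ccnd3 gained 1 and lost 1 of 14. Ribosome biogenesis genes gained 4 and lost 1 of 50 (3 and 1 adjusted over the list alone). Of 20 genes, 2 had only gains (Wdr43 with 3 of 6 regions and Utp20 with 1 of 3), 1 only losses (Polr1a, 1 of 5), 16 neither, and 1 had no region.

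Relative to all regions each of these 5 lists fell: glutamine by 0.15 (5 of 8 libraries, exact permutation adjusted p = 0.0167), glycolysis by 0.28, mTORC1 by 0.31 and ribosome biogenesis by 0.23 (8 of 8 libraries and exact permutation adjusted p = 0.000668 for each of these 3), and cell cycle by 0.19 (7 of 8 libraries, exact permutation adjusted p = 0.00113). With equal peaks the glycolysis and cell cycle falls ended (0.00 and exact adjusted p = 0.938 for both), while glutamine (−0.11), mTORC1 (−0.30) and ribosome biogenesis (−0.22) stayed past the threshold. With the stricter peak threshold the glutamine fall did not pass (−0.08, exact adjusted p = 0.156).

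Markers of other cell types moved in different directions. B cell markers gained 16 and lost 1 of 67 regions. Of 15 genes, 3 had only gains, 1 both and 8 neither, and 3 had no region, among them Ms4a1 and Cd79b. Bank1 gained 9 and lost 1 of 20 regions, Ebf1 gained 5 of 13, Blk 1 of 5 and Fcrla 1 of 3. The list rose by 0.50 (1.41-fold, 8 of 8 libraries, exact permutation adjusted p = 0.000668) and by 0.68 with equal peaks, but stood at −0.14 among regions within 1 kb of a gene boundary (exact adjusted p = 0.201). Myeloid markers gained 9 and lost 7 of 61 regions (12 and 7 adjusted over the list alone). Of 15 genes, 3 had only gains, 3 both and 9 neither. Itgam gained 3 and lost 4 of 13 regions, Siglech gained 2 and lost 1 of 4, Fcgr3 gained 1 and lost 2 of 7, and Mpeg1 gained 1 of 2. The myeloid list fell by 0.40 (8 of 8 libraries, exact permutation adjusted p = 0.000668) and was at −0.29 with equal peaks. CD8 and NK cell markers gained 9 and lost 3 of 54 regions. Of 12 genes, 4 had only gains, 1 only losses, 2 both and 5 neither. Klre1 gained 3 of 9 regions, Klrk1 2 of 4, and Klrb1c and Cd8b1 each gained 1 and lost 1, of 8 and 9. This list fell by 0.12 (3 of 8 libraries, exact permutation adjusted p = 0.039) and stood at −0.24 with equal peaks. It turned to +0.02 with the stricter peak threshold, and the call ended when any of 10 libraries was left out: wild-type 2 or 4 or knockout 1 or 4 at 0 h, or wild-type 1, 2 or 3 or knockout 2, 3 or 4 at 72 h (−0.08 without wild-type library 4 at 0 h, exact adjusted p = 0.0992).

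Across the 11 alternative settings, 5 lists kept their direction and stayed past the threshold in each: T cell identity, naive, T cell receptor, Th1 and mTORC1, with exact permutation adjusted p from 0.000525 to 0.0201. Th2 ranged from −0.26 to 0.42 (exact adjusted p from 0.000525 to 0.565, past the threshold in 10), Th17 from −0.16 to 0.25 (0.0022 to 0.833, in 1) and B cell markers from −0.14 to 0.93 (0.000565 to 0.201, in 10). The regulatory list ranged from −0.61 to −0.03 (exact adjusted p up to 0.593, in 10), the follicular list from −0.51 to −0.09 (up to 0.109, in 10) and IRF family genes from −0.42 to 0.01 (up to 0.938, in 10). Glutamine genes ranged from −0.37 to −0.08 (up to 0.156, in 9), glycolysis from −0.35 to 0.00 (up to 0.938, in 10), cell cycle from −0.46 to 0.00 (up to 0.938, in 9) and ribosome biogenesis from −0.51 to −0.08 (up to 0.0725, in 10). Myeloid markers ranged from −0.80 to −0.29 (exact adjusted p up to 0.107, in 10), CD8 and NK cell markers from −0.24 to 0.06 (up to 0.745, in 6) and interferon-stimulated genes from −0.24 to 0.06 (0.00147 to 0.982, in 2).

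Counts of changed regions at single genes rested on few libraries. Leaving out 1 library moved such a count by over 1.5 times in 231 of 1350 values, and equal peaks did so in 58 of 90. Leaving out any of at least 10 of the 15 libraries moved the number of changed regions at Cd8b1 (range 0 to 1), Pfkfb3 (0 to 2), Ccnd3 (1 to 2), Itgam (1 to 5), Pdcd1 (1 to 3), Irf4 (1 to 2), Blk (0 to 1), Txk (3 to 6), Nt5e (2 to 3), Siglech (1 to 2) and Egr2 (3 to 5). Fewer libraries did so at Il21 (3 to 5), Cdk6 (3 to 4), Fcrla (0 to 1), Ctla4 (3 to 6), Bcl11b (4 to 7), Icos (5 to 7), Slc38a1 (1 to 2), Ccne1 (3 to 5), Irf2 (3 to 6) and Oasl2 (0 to 2). The same held for 1 or 2 libraries at Foxp1 (13 to 20), Eif4e (2 to 4), Deptor (1 to 2), Utp20 (1 to 2), Bank1 (6 to 9) and Ebf1 (2 to 5).

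**Figure D2:**
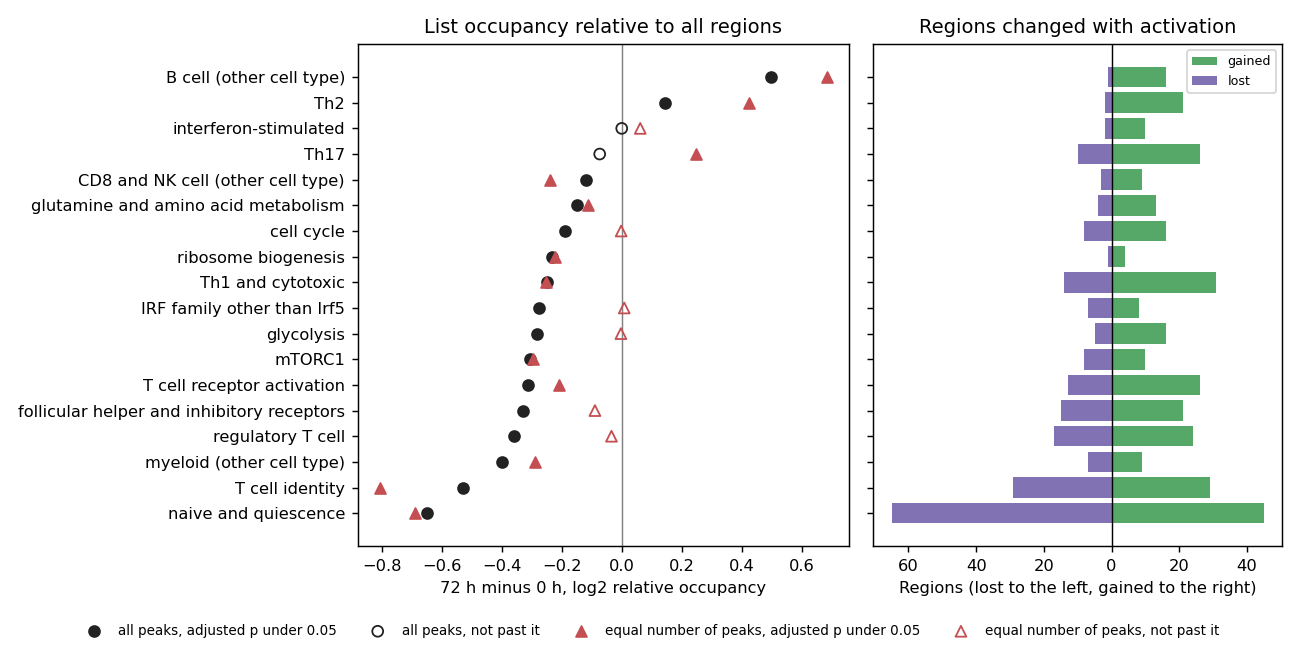
Left, 72 h minus 0 h difference in log2 relative occupancy for each of the 18 lists with all peaks (black circles) and with 29994 peaks per library (red triangles), filled where the adjusted exact p is under 0.05. Right, numbers of regions gained (green) and lost (purple) per list. The naive and quiescence list is lowest with all peaks (−0.65) and the B cell list highest (+0.50), while Th17 lies at −0.07 with all peaks and at +0.25 with equal peaks, IRF family genes at −0.28 and +0.01, and interferon-stimulated genes at 0.00 and +0.06.

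Libraries of the same time shared far more peaks with each other than across times. In wild type the mean Jaccard index of bases was 0.673 within times and 0.469 between them, and in knockout 0.621 and 0.441. Each difference (0.204 and 0.179) was the largest of 35 splits, a share of 0.0286. The share of a library's peaks within 1 kb of a gene boundary fell by 4.70 points in wild type, from 26.3% ± 1.55 to 21.6% ± 0.987 (SD, n = 4 each), and by 6.54 points in knockout, from 29.7% ± 4.62 (SD, n = 3) to 23.1% ± 0.901 (SD, n = 4), with an exact permutation p = 0.0286 each (adjusted 0.0571 over 4 comparisons). With equal peaks these differences were −0.43 and −0.57 points (exact p = 0.4 and 0.257).

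The comparison of knockout with wild type at 0 h asked whether loss of IRF5 altered chromatin before activation. Knockout libraries had less of the genome in peaks: 22.6 ± 5.80 Mb (SD, n = 3) against 30.8 ± 2.83 Mb (SD, n = 4), or 0.717-fold, with every knockout library below every wild-type library (exact permutation p = 0.0286). The size of this difference rests largely on knockout library 3 (15.9 Mb): without it the ratio was 0.844 (exact permutation p = 0.133), and without knockout library 1 or 4 it was 0.666 or 0.657. The number of peaks, 39313 against 45746 (0.848-fold), did not differ beyond the spread (exact permutation p = 0.286), and its log2 difference ran from −0.36 without knockout library 1 to −0.054 without knockout library 3. At 0 h 327 regions were called in all 4 wild-type and no knockout libraries, and 4 in all 3 knockout and no wild-type libraries. A region called in exactly 4 of these 7 libraries would be wild-type only by chance with a share of 0.0286. With equal peaks the counts were 84 and 30. Leaving out a library removes a condition of these counts, so a rise is favoured by construction and does not by itself mark that library. The wild-type-only count rose to 864 or 534 without wild-type library 1 or 3, and to 1321 or 860 without knockout library 1 or 4. The knockout-only count rose to 9, 18 or 9 without wild-type library 2, 3 or 4, and to 17, 157 or 25 without knockout library 1, 3 or 4.

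The strongest wild-type-only region at 0 h lay inside Snd1, which encodes a staphylococcal nuclease domain protein of RNA processing, on chromosome 6 from 28929168 to 28929750 (−log10 q of 289 in the merged wild-type list). The next, from 34881005 to 34881510 on chromosome 4 inside Zfp292, had a −log10 q of 88.8 and was called in all 8 activated libraries. The remaining 8 lay in Snd1 again (28931866 to 28932197), in Fndc3b, Serhl, Prkcb, Tex2 and Akap7, and nearest to Adora2a, an adenosine receptor gene, and Tmem144. The knockout-only regions included ones in Rsbn1l and Tgds and another 125614 bp from H2al2a. Among genes of the fixed lists, 11 had a wild-type-only region at 0 h. They included Tbx21, the Th1 master regulator, Il1rl1, the interleukin-33 receptor gene, Lag3, Thy1, Bach2, Satb1, Foxo1, Ets1, Gpt2 and the B cell gene Blnk, each with 1 region. When 1 library was left out the number ranged from 1 to 3 at Satb1, 1 to 2 at Ets1 and Gpt2, and 0 to 1 at Foxo1.

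At 72 h, the same comparison asked whether IRF5 altered the activated state. Knockout libraries again had less of the genome in peaks, 31.5 ± 2.08 against 37.0 ± 1.66 Mb (SD, n = 4 each), or 0.850-fold, without overlap between the groups (exact permutation p = 0.0286). The number of peaks was 59799 against 66068 (0.906-fold, exact permutation p = 0.114), and the adjusted exact p for bases was 0.0286 over the 4 comparisons. Without wild-type library 4, which had the fewest peaks of its group, the log2 difference in peaks was −0.19 and passed (exact p = 0.0286). At 72 h 387 regions were wild-type only and 25 knockout only, and 263 of the 387 had no peak in any of the 7 untreated libraries. With equal peaks the counts were 90 and 69. As at 0 h, leaving out a library favours a rise of these counts by construction. The wild-type-only count rose to 692, 628 or 981 without wild-type library 1, 3 or 4, and to 690, 627, 749 or 626 without knockout library 1, 2, 3 or 4. The knockout-only count rose to 66, 49, 77 or 41 without wild-type library 1, 2, 3 or 4, and to 117, 59, 60 or 62 without knockout library 1, 2, 3 or 4.

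The strongest wild-type-only regions at 72 h were on chromosome 16 from 49535525 to 49535903, 122838 bp from Gm4802 (−log10 q of 232 in the merged list), and on chromosome 9 from 56938204 to 56938625 over the end of Imp3 (166). The Snd1 region was next (103), followed by regions in Gm960, Thra, Bach2, Ubac2, Atxn1 and Csnk1g1 and near Dynll2. Among knockout-only regions, the strongest in the merged knockout list lay in Trio (chromosome 15, 27827583 to 27828644, −log10 q of 46.9), which was also called in all 7 untreated libraries. The others lay in Arfgef1, Epm2a, Aff1, Hbs1l, Ksr2 and Tnfrsf12a and nearest to Sptssa, Nars2 and Tpd52. In the fixed lists, 8 genes had wild-type-only regions at 72 h: Bach2 with 3, and Foxp1, Cd28, Batf, which encodes an AP-1 factor of effector T cells, Fasl, Nrp1, Hif1a and Tyrobp with 1 each (1 to 2 at Foxp1 and Hif1a when 1 library was left out). Ikzf4, a regulatory T cell gene, had the 1 knockout-only region.

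Over both times together, no region passed the exact test of genotype stratified by time after Benjamini-Hochberg adjustment, with 0 regions higher and 0 lower in knockout. At an unadjusted p under 0.05 the exact test gave 1168 regions, 31 called more often and 1137 less often in knockout. These are 1.39% of the tested regions. Simulated data with a library-wide shift but no changed region gave 1.63%, but there each region kept 1 rate at both times. The real changes between 0 h and 72 h were not simulated, so 1.63% is not the share to be set against 1.39%. It also says nothing about the uneven direction. An unstratified Fisher's exact test over all libraries also gave 0 in each direction after adjustment. The smallest exact p the design allows is 0.000408, so about 684 regions would have to reach it for a call. Only 2 regions reached it, called in every wild-type and no knockout library at both times: the Snd1 region, 596 kb from Irf5, and a region inside Agap3 (chromosome 5, 24486031 to 24486633). None was knockout only at both times. With equal peaks the Snd1 region was called in all 4 wild-type libraries at 0 h, in 2 of 4 at 72 h and in no knockout library, and neither region then met the rule at both times. The count of 2 rose to 5 without wild-type library 1 at 0 h, 7 or 4 without knockout library 1 or 4 at 0 h, and 4 without wild-type library 1 or 4 at 72 h. Here too a library left out favours a rise by construction. Over both times, knockout libraries covered fewer bases (0.781-fold, stratified exact permutation p = 0.000408) and had fewer peaks (0.877-fold, exact p = 0.0286), and the difference in bases did not itself differ detectably between times (exact p = 0.509).

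**Figure D3:**
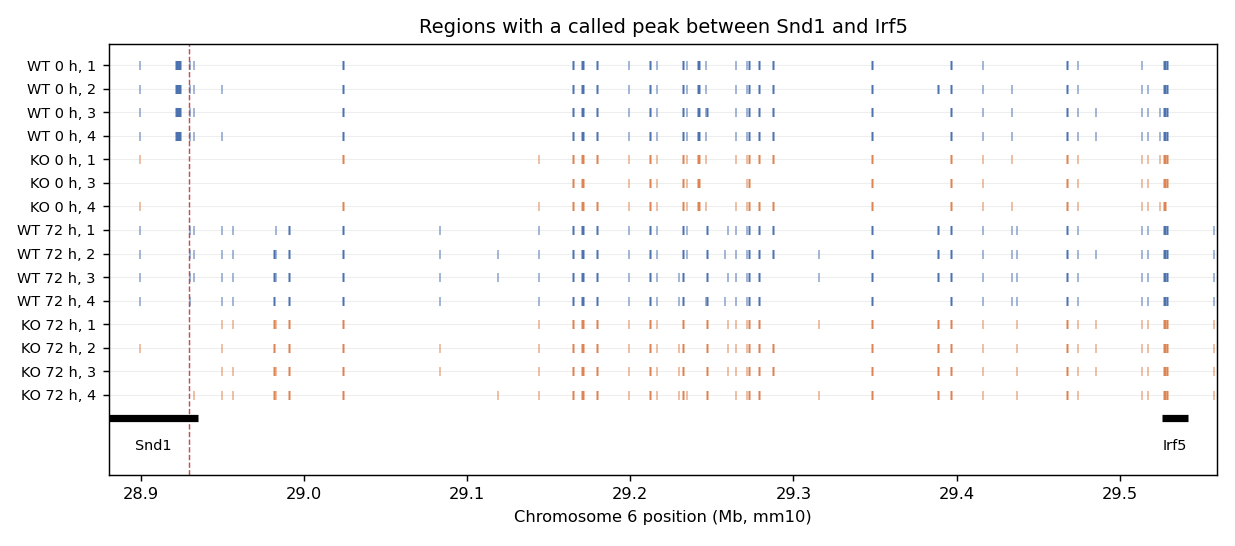
Regions with a called peak in each library (lines; blue, wild type; orange, knockout) along chromosome 6 from Snd1 to Irf5, with position in Mb (mm10) on the horizontal axis and the genes as black bars. The dashed line marks the region from 28929168 to 28929750, called in 8 wild-type and 0 of 7 knockout libraries.

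None of the fixed lists of T cell genes differed by genotype. The lists other than B cell markers differed by −0.07 (IRF family) to 0.06 (CD8 and NK cell) in log2 relative occupancy, with exact permutation adjusted p of 0.697 to 0.944. Regulatory and follicular lists stood at 0.03 and 0.06, Th1 at 0.01, Th2 at −0.03, Th17 at −0.04, interferon-stimulated genes at 0.02 and glutamine genes at −0.04. No list had a region that differed by genotype adjusted over the list alone. The design largely fixed this for the longer lists, where a lone region at the smallest exact p of 0.000408 cannot pass. The 2 regions at that p lay at Snd1 and Agap3, which are in no list. The B cell list was lower in knockout (0.834-fold, −0.26 on the log2 scale, 7 of 7 knockout libraries below every wild-type library of their time, exact permutation adjusted p = 0.00735). That difference was −0.03 with equal peaks (exact adjusted p = 0.83) and −0.16 with the stricter threshold (exact adjusted p = 0.523), and over the 11 alternatives it ranged from −0.60 to −0.03 (exact adjusted p from 0.00735 to 0.83, past the threshold in 6). With the stricter threshold the naive list was higher in knockout (+0.07, exact adjusted p = 0.0147), and with regions counted only where at least 0.5 of their length was covered the T cell identity list was lower (−0.16, exact adjusted p = 0.0331). Each was the only passing value of its list in 11 alternatives. The genotype effect on a list differed between 0 h and 72 h for none of the 18 (lowest exact p 0.0445 for Th2, adjusted 0.426).

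Averaged over both genotypes, libraries of the same genotype shared slightly more bases than libraries of different genotype. At 0 h the mean Jaccard index was 0.674 within genotypes and 0.624 between them, and at 72 h 0.634 and 0.616. By genotype, the 0 h index was 0.702 among wild-type and 0.616 among knockout libraries, the latter below the 0.624 between genotypes. The low knockout mean rests on library 3: the pair without it had an index of 0.710, and the lowest pair with it 0.563. At 72 h it was 0.644 among wild-type and 0.623 among knockout libraries. Both differences (0.0493 and 0.0173) were the largest of 35 splits, a share of 0.0286. Unequal coverage also lowers the index, and knockout libraries covered fewer bases, so the splits may partly restate that difference. At 0 h the difference was 0.0158 without knockout library 3, 0.0246 or 0.0276 without wild-type library 2 or 4, and 0.0876 or 0.0937 without knockout library 1 or 4. With a library left out there are too few splits at 0 h for a share under 0.05, and at 72 h the real split was no longer alone at the top when wild-type library 2, 3 or 4 was left out (differences 0.0107, 0.0123 and 0.0141, share 0.0571 each). The share of peaks near gene boundaries did not differ by genotype at 0 h (3.38 points higher in knockout, exact permutation p = 0.229; 0.724 points without knockout library 3 and 4.97 without knockout library 1) or at 72 h (1.54 points, exact p = 0.0857).

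The authors' final lists, 1 per condition and so compared without a replicate check, held 40146 peaks for wild type and 37573 for knockout at 0 h, and 55442 and 49013 at 72 h. Of the knockout peaks, 95.5% at 0 h and 94.5% at 72 h overlapped a wild-type peak by at least 1 bp. Of the wild-type peaks, 87.2% and 82.9% overlapped a knockout peak, leaving 5119 and 9488 without one. The merged lists behind these lists pool unequal data. At 0 h they hold 97.6 M kept fragments from 4 wild-type and 73.7 M from 3 knockout libraries, and at 72 h 102 M and 90.8 M. How far this sets the unequal overlap was not tested. Across time, 58.6% of the wild-type and 59.4% of the knockout 72 h peaks overlapped a 0 h peak of the same genotype, and 80.3% and 77.8% of the 0 h peaks overlapped a 72 h peak.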

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

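The tests of the region counts over both times (activation, genotype, and regions seen in every library of 1 genotype and none of the other) were chosen before the data were examined. The gene lists and the alternative settings used below were also set before then, except the equal number of peaks without the smallest library. The use of their values to weigh explanations, and all other tests in this part, were chosen after the results were seen.

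Single libraries stood far from the others of their group in 6 of 72 groups of values, where chance would give about 3.6, so the number itself is unremarkable. The knockout group at 0 h, with 3 libraries, was too small for this rule and was not examined. Its library 3 had 29994 peaks, against 42357 and 45589 in the others. Wild-type library 1 at 0 h had 39807 peaks, against 47625 or more in the other libraries of its group. It also had the highest share of peaks near gene boundaries (28.6%, others up to 25.7%) and the lowest relative occupancy of IRF family genes (0.23, nearest 0.36). Knockout library 1 at 72 h had 55519 peaks, against 60859 or more, and the highest occupancy of T cell identity genes (−0.12, nearest −0.19). Wild-type library 1 at 72 h had the lowest occupancy of the follicular helper list (−0.056, nearest 0.019).

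Chance division of the libraries can be excluded for activation: 1 of 100 splits, the real one, gave as many regions (19275, highest other 0). Within wild type 1 of 35 splits separated as many regions (14786, highest other 180), and within knockout 1 of 35 (12659, highest other 2108). For the adjusted genotype test the splits decide nothing, because with a real count of 0 every split gives as many (100 of 100, highest other 0). For the separating regions at 0 h chance could not be excluded, since 6 of 35 splits gave as many (331, highest other 736). At 0 h the largest split set wild-type library 1 with knockout libraries 3 and 4, the 3 untreated libraries with the fewest peaks, so the untreated libraries hold a structure that follows the number of peaks. At 72 h 1 of 35 splits, the real one, gave as many (412, highest other 297). This is the smallest share possible (0.0286), without adjustment over the 4 comparisons, and splits were not counted with equal peaks, so chance is excluded only for the count with all peaks and only by this narrow margin. For regions separating the genotypes at both times, 4 of 100 splits gave as many (2, highest other 2), a share under 0.05 that rests on 2 regions.

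The first pattern weighed is the lower coverage and the surplus of wild-type-only regions in the comparison with knockout. At 72 h knockout libraries kept fewer fragments, and 72.6% of the wild-type-only regions (281 of 387) had a peak in the merged knockout list, with a median −log10 q of 24.7 in the merged wild-type list against 78.1 over regions called in all 4 wild-type libraries. Most of these regions thus had some signal in knockout, while 106 had no peak in the merged knockout list. That list pools 90.8 M fragments, so a region with a real but partial decrease would also have a peak in it. These values therefore cannot tell weak peaks left uncalled by fewer fragments from such a decrease. At 0 h every knockout library covered fewer bases than every wild-type library, yet in 6 of the 12 pairs the knockout library had more kept fragments, which argues against fewer fragments as the whole cause, though knockout library 4 had the fewest. An effect of IRF5 on chromatin and other differences in library quality both remain open at 0 h, where knockout libraries had shorter fragments (mean 153 against 170.5 bp, exact permutation p = 0.143) and narrower peaks (median 481 against 576 bp, exact permutation p = 0.0857), and where knockout library 3 carried much of the difference in bases (0.844-fold without it).

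The second pattern is the region inside Snd1, called in 8 wild-type and no knockout libraries. A weak peak near the calling threshold is argued against: 0 of 2 merged knockout lists had a peak there, and its −log10 q was 289 at 0 h (median 135 over regions called in all 4 wild-type libraries) and 103 at 72 h. With an equal number of peaks it was called in all 4 wild-type libraries at 0 h but in 2 of 4 at 72 h. It lies 596 kb from the targeted gene, so a segment of chromosome from another strain around Irf5 could carry a sequence difference there. Within 5 Mb of Irf5, 8 of 318 regions had an unadjusted exact p under 0.05, and 11.6% of windows of that size had as many (2.39% for 1 Mb, where 6 of 138 did), but 5 of these regions are those at Snd1 that prompted the test, so this could not be told apart from an effect of IRF5.

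The third pattern is the B cell list. B cells in the cultures could not be told apart from other causes of its rise with activation: of the 10 genes with a region outside Bank1 and Ebf1, 2 gained one, but the mean number called at Pax5 went from 2.75 to 4 in wild type and from 1.33 to 4 in knockout, while at Cd72 it fell from 3.25 to 1.25 and from 1.67 to 1. More peaks per library do not explain the rise, since it was 0.68 with equal peaks (exact permutation adjusted p = 0.00105; 0.000565 to 0.201 over 11 alternatives). No other biological explanation was tested. The lower occupancy in knockout is consistent with fewer peaks per library, since with equal peaks it was −0.026 (exact permutation adjusted p = 0.83; 0.00735 to 0.83 over 11 alternatives).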

How the results depend on the processing

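The alternative with an equal number of peaks in 14 libraries, without knockout library 3 at 0 h, was chosen after the results were seen, and the other alternatives before the data were examined. Directions of the peak and list results mostly held, and the number of peaks per library was the choice that moved most counts. Depth limits weak peaks, and a region without a peak is not shown to be closed. The cause was not tested unless given here. The motif comparison over whole regions was not run.

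With an equal number of peaks, activation gained 6637 and lost 6349 regions. Wild-type-only regions numbered 84 at 0 h, 90 at 72 h and 0 at both times, and knockout-only regions 30 and 69. The lists gave 0 genotype calls, Th17 stood at 0.25 and IRF family at 0.0080 after activation, and the change in peaks near boundaries at −0.43 points in wild type and −0.57 in knockout. By construction this setting removes differences in peak number. With equal peaks in 14 libraries the counts were 6915 gained, 6527 lost, 167 knockout only at 0 h, 85 knockout only and 110 wild-type only at 72 h, 0 wild-type only at both times and 0 lists by genotype. The change near boundaries was −0.062 points in wild type and 0.20 in knockout, and the Jaccard difference 0.0170 for genotype at 0 h and 0.191 for activation in knockout, where 15 splits are too few for a share under 0.05.

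With coverage of at least 0.5 of the region, 8843 regions were gained, and 895 at 0 h, 652 at 72 h and 11 at both times were wild-type only. By genotype 2 lists passed, T cell identity at −0.16, and CD8 and NK cell stood at 0.060 after activation. With the stricter threshold 2 regions at 0 h and 15 at 72 h were knockout only, 4 were wild-type only at both times, and CD8 and NK cell stood at 0.019. With regions in at least 4 libraries, 0 were knockout only at 0 h, since the 4 such regions had no peak at 72 h. Within 1 kb of a gene boundary, 0 lists passed by genotype, Th2 stood at −0.26 and B cell at −0.14 after activation. Counting bases in place of peaks, the genotype difference was −0.48 at 0 h and −0.23 at 72 h, and passed. Counting overlap only over 0.5 of a peak, the final lists shared 82.4% (wild type in knockout) at 0 h, and 94.2% (knockout in wild type) and 81.2% (wild type in knockout) at 72 h. Across time the shares were 57.1% and 77.9% in wild type (72 h in 0 h, 0 h in 72 h) and 56.0% and 76.7% in knockout.

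With the replicate number as a block (replicate block), 0 regions were gained and 0 lost, and 0 lists passed by genotype. The log2 rise in peaks was 0.53 in wild type (exact p = 0.125) and 0.61 in knockout (exact p = 0.25), and the change near boundaries −4.70 and −6.35 points (exact p = 0.125 and 0.25). For peaks and boundaries so few arrangements within pairs cannot give a p under 0.05, which says nothing about stability. The list tests pool the pairs and can pass: 15 lists did for activation. For regions the smallest p with 7 pairs was 0.0156, which 9262 regions reached, and 26170 would have been needed at it, so the 0 follows from the design. Correlations of libraries with the same number were −0.135 to 0.0689 between genotypes at 0 h and −0.0363 to 0.0242 at 72 h (other numbers up to 0.187 and 0.0483), and 0.000658 to 0.00648 between times in wild type and −0.00425 to 0.0291 in knockout (others up to 0.00855 and 0.0165). The best match had the same number for 1 of 3, 1 of 4, 2 of 4 and 1 of 3 libraries, so the numbers were not taken as pairs.

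Leaving out each library in turn, the log2 difference in peaks ranged from −0.19 (without wild-type library 4, passing) to −0.11 for genotype at 72 h and from 0.44 to 0.75 for activation in knockout. The difference near boundaries ranged from 1.11 to 2.02 points for genotype at 72 h and from −8.13 to −3.88 for activation in knockout. The Jaccard difference ranged from 0.0158 to 0.0937 for genotype at 0 h, 0.0107 to 0.0238 at 72 h, and 0.167 to 0.187 for activation in knockout. These activation measures in knockout cannot pass with 1 knockout library fewer. Knockout-only regions ranged from 4 to 157 at 0 h and 25 to 117 at 72 h, wild-type-only regions from 326 to 1321 and 387 to 981, and those at both times from 2 to 7. Such counts tend to rise by construction when a library of either group is left out. Gained regions ranged from 12268 to 14777 and lost regions from 2633 to 3613, and 15 to 17 lists passed for activation.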

Other observations

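The genes in this part were chosen after their values were seen, and so was every test and count given here.

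Several signature genes of T helper subsets lay outside the rule for naming genes. Il17f, a Th17 cytokine gene, gained 2 of its 3 regions and lost none. None of its regions was called at 0 h, and a mean of 2.5 in wild type and 2 in knockout were called at 72 h. The neighbouring Th2 cytokine genes Il4 and Il13 each gained 1 region, of 2 and 3, and Il5 gained and lost 0 of 3. Foxp3, the master regulator of regulatory T cells, lost 2 of 4 regions, the mean number called going from 3 to 1 in wild type and from 2.67 to 0.75 in knockout. Among cytotoxic genes, Gzmb gained 2 of 8 regions and Prf1 lost 1 of 3. Ifngr1, an interferon-γ receptor gene, lost 3 of 16, and Klf2, a quiescence factor, 1 of 8. Myc, with 12 regions, Cd8a with 4 and Pax5 with 5 had no region that passed.

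Near Snd1, 2 further regions were called in all 4 wild-type and no knockout libraries at 0 h. The one from 28920986 to 28924256 on chromosome 6 had no peak in any library at 72 h, and the one from 28931866 to 28932197 was called in 3 wild-type libraries and 1 knockout library at 72 h. Within 1 Mb of Irf5, 6 of 138 regions (4.35%) had an unadjusted exact p under 0.05 for genotype, against 1.39% of all tested regions, and 2.39% of windows of that size had as many. Of the 6, 5 are at Snd1, the gene that prompted the count, so the excess mostly restates that observation.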
